A study of Lachancea waltii with 6 samples.

How the data were processed

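The samples were DNA from the yeast Lachancea waltii, a relative of the budding yeast Saccharomyces cerevisiae. Per the labels, cells in rich medium received 200 mM hydroxyurea, a ribonucleotide reductase inhibitor that slows replication forks, and were harvested after 120, 180 or 240 min. The comparison DNA, labelled as G1 phase, came from cells held for 20 hours in medium low in ammonium sulfate. Per the labels' protocols, DNA was extracted from nuclei so that single-stranded regions were kept, purified on a caesium chloride gradient, cut with EcoRI and labelled without denaturation, so that incorporation of dye depended on single-stranded DNA (ssDNA). Each of the 3 time points was hybridised on 2 arrays of opposite dye orientation, 6 arrays in all. No label named a second culture or extraction, so the arrays of a time point were treated as a technical dye swap and counted as 1 sample. Replicate numbers were given in accession order and only name arrays. The labels did not say whether the G1 DNA was shared between time points.

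The deposited files were the scanner output of each array, made with Agilent Feature Extraction 10.5.1.1 and its 2-colour protocol, per the file headers. They gave spot and background intensity in the Cy3 and Cy5 channels, and processed intensity values that were background-subtracted, detrended and dye-normalized by that software, per the file headers. The deposited log10 ratio of red over green processed signal, per the file headers, served to check the sign and scale of the ratios computed here. The log2(S/G1) ratios of the 180 min arrays correlated across probes with r = -0.45 from background-subtracted and -0.39 from processed intensity. A single factor per array would leave this r as it is, so the processing was more than that. Detrending and dye normalization were not told apart. The arrays carried 33062 genomic probes of 60 bases with a median spacing of 301 bp, named by chromosome and position over 8 chromosomes and 10.2 Mb. The assembly behind these positions was not given in the sources used here, and no genome sequence or annotation was used here. Genes, centromeres, rDNA, tRNA genes, histone genes, the mating-type locus and mitochondrial DNA were therefore not analysed here, and sequence content was read from the probe sequences alone.

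The log2 ratio of processed signals was turned to S over G1 on every array from the dyes in the labels and centred on the array's median, with no loess or quantile step. Outlier-flagged spots and control spots were left out. Between 5 and 119 spots per array were flagged, and no spot was saturated. A probe flagged on either array of a time point was left out of that time point. The arrays of a time point were averaged per probe, and the mean track gave the 3 time points equal weight. Tracks were moving means over 4 kb, evaluated every 0.5 kb with at least 5 probes. A peak was the highest point within 5 kb on either side, above the lowest height at which the same call on the dye-difference track gave at most 5% as many maxima. That track is the difference between the 2 orientations divided by 2, and holds dye bias and array noise. S-phase signal cancels from it only where both arrays carry that signal at the same size. Peak positions are given as the summit with the 4 kb window around it. Widths were measured at 50% of the summit height, with edges searched up to 15 kb from the summit. The profile around summits was the mean of unsmoothed probe values in bins of 1 kb on both sides.

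Summits were called shared when within 2 kb, and the number shared was set against 1000 circular shifts of one list along the chromosomes placed end to end. Chromosome ends, defined as 20 kb from the outermost probe, the S. cerevisiae ARS consensus and AT content at summits were tested against 10000 circular shifts, two-sided. These 5 position tests on the mean track formed 1 family for Benjamini-Hochberg adjustment. Per-probe tests used limma 3.58.1 in R 4.3.3: an intercept over the 3 dye-swap means, moderated by eBayes, with Benjamini-Hochberg adjustment over 32875 probes and a threshold of 0.05. Height and width by time had 1 sample per time point and were not tested. They were compared by whether the 2 arrays at one time lay on one side of the 2 at another, which chance gives for 33.3% of peaks counting both directions if the 4 arrays are exchangeable. The dye effect was shared between times, so they are not, and that share is only a rough guide. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

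Regions were named by a rule set before the data were examined: the 12 highest peaks of the mean track, the 6 largest rises and the 6 largest falls from 120 to 240 min among mean-track peaks with non-overlapping arrays, the highest peak of each time point, the lowest region of the mean track, and for chromosome ends the median with the highest and lowest member. Regions chosen after their values were seen are marked as such.

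Array signals have no count depth, and the number of arrays limits the precision. At least 98.9% of probes were well above background in each channel of each array. Median spot signals lay between 1181 and 3094 against median local backgrounds of 28 to 32. Both 120 min arrays lay on slide 1 and the 180 and 240 min arrays on slide 2, each slide scanned in 1 scan. A comparison of 120 min with a later time cannot be told apart from a comparison of slides, while 180 against 240 min is within slide 2.

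The per-probe test was tested on simulated data made from the 3 time points, with 50 of 32875 probes changed at each size. It recovered 100% of probes changed by 1 or 1.5 on the log2 scale, 74% of those changed by 0.5 and 78% of those changed by -0.5, with 0 false calls. The simulated values held no bias common to the 3 time points, so the 0 false calls do not cover such a bias. The peak call was tested on simulated tracks with 25 peaks of each height added to noise. Noise in the called track came from differences of a time point from the mean of the 3, with values beyond 0.3 set to 0. The dye difference cancelled from that track and entered the null alone. With noise of the 120 min pair it recovered 28% of peaks of height 0.2 and 100% of those of height 0.3, 0.5 and 1. With noise of the 240 min pair it recovered 4% at 0.2, 96% at 0.3 and 100% at 0.5 and 1. With noise of the 180 min pair it recovered 0% at 0.2, 0.3 and 0.5 and 100% at 1, and no time point gave a false peak. The null was noisier than the called track by construction, so the lack of false peaks does not describe the real call. The simulated tracks set thresholds of 0.19 at 120 min, 0.61 at 180 min and 0.23 at 240 min, above the 0.16, 0.45 and 0.19 of the real tracks, so these shares do not give the recovery of the real call at heights between the thresholds.

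Alternatives covered normexp background correction with an offset of 50, lowess within arrays, no centring, dim and outlier spots, correction for probe GC content, the smoothing window, the null and threshold for peaks, single arrays and time points, dye orientations and the variance model. Added after the data were seen were background-subtracted signals before dye normalization and the 180 min pair with its sign turned. So were heights and the profile by dye orientation, the profile around summits called at 120 min, and chromosome ends under further corrections.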

Results

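The data were 6 two-channel arrays that measured single-stranded DNA (ssDNA) across the 8 chromosomes of Lachancea waltii. Hydroxyurea slows replication forks and lets ssDNA build up at them, and a ratio of S-phase over G1 signal above the array median is read as ssDNA gained in S phase at that place. The series asked where that ssDNA lay after 120, 180 and 240 min in 200 mM hydroxyurea. Each time point was 1 sample, read on 2 arrays of opposite dye orientation. Values below are log2(S/G1) relative to the array median, the error is the half-range of the arrays of a time point, and p-values over the 3 time points measure the spread between these time points only.

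The direction of the ratios came from the dyes in the labels. The arrays at 120 min correlated across probes with r = 0.26 and those at 240 min with r = 0.41, but those at 180 min with r = -0.39, which passed the limit of -0.3 set before the data were examined for calling a direction unsettled. By that rule the direction at 180 min is unsettled. Turning both arrays leaves this r as it is, however, so it does not bear on the sign of the pair. In the direction of the labels, 93 of the 93 summits called at 180 min lay within 2 kb of a summit at 240 min, with both 180 min arrays above 0, and the direction of the labels was kept. After 4 kb smoothing the 180 min arrays correlated with r = 0.53. Arrays with the same S-phase dye correlated between times with r between 0.66 and 0.82, and the difference between dye orientations correlated between times with r between 0.74 and 0.82. These correlations are across probes, which are not independent replicates. With the 180 min pair turned to G1 over S, 0 peaks were called at 180 min and 16 in the mean track.

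S-phase ssDNA was concentrated in discrete peaks a few kilobases wide. The mean of the 3 time points held 110 peaks, 1 per 92.7 kb, with a median height of 0.84, a 1.79-fold S over G1 ratio. Every chromosome had peaks, from 10 on chromosome 3 (1 per 129 kb) to 18 on chromosome 1, and chromosome 6 was the densest with 16 (1 per 71.5 kb). The spacing between neighbouring summits had a median of 64.5 kb and ranged from 10.0 to 347 kb. The longest stretch without a peak lay on chromosome 7 between 541000 and 888000. Of the 110 peaks, 107 lay above 0 on all 6 arrays and 73 reached at least 0.70. The height threshold was 0.26, and the dye-difference track gave 3.5 maxima above it, 3.18% of the peaks. A bias common to both orientations cancels from that track, so this share does not cover it. Between 0.2 and 0.3 there were 17 maxima and 74 minima of turned sign, and between 0.3 and 0.4 11 and 12. The lowest peaks are therefore the least certain. With local minima as the null, 98 peaks were called in the mean track.

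**Figure D1:**
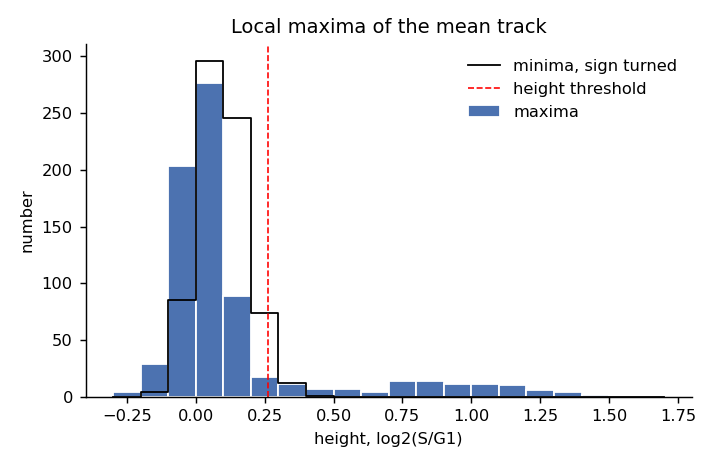
Number of local maxima of the mean track (bars) by height in log2(S/G1), with the local minima after turning their sign (line) and the height threshold of 0.26 (dashed). Maxima above 0.70 had no counterpart among the turned minima.

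The highest peak was on chromosome 3 with its summit at 299000 (297000 to 301000) and a mean height of 1.60, 3.03-fold. It was also the highest at 180 min, with 1.81 ± 0.08, and at 240 min, with 1.98 ± 0.08. At 120 min the highest point lay beside it at 298500, with 1.05 ± 0.01. Chromosome 2 held 3 of the 12 highest peaks close together, at 529000 with a height of 1.43, at 607500 with 1.32 and at 588500 with 1.28. Chromosome 4 held a pair of them, at 780500 with 1.42 and at 463000 with 1.35. Chromosome 6 held 3, at 1016000 with 1.37, at 690000 with 1.29 and at 232500 with 1.22. The remaining members of the 12 were on chromosome 8 at 232000 with 1.33 and at 335000 with 1.30, and on chromosome 3 at 695500 with 1.30. What genes or other features lay at these sites was not analysed here.

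**Figure D2:**
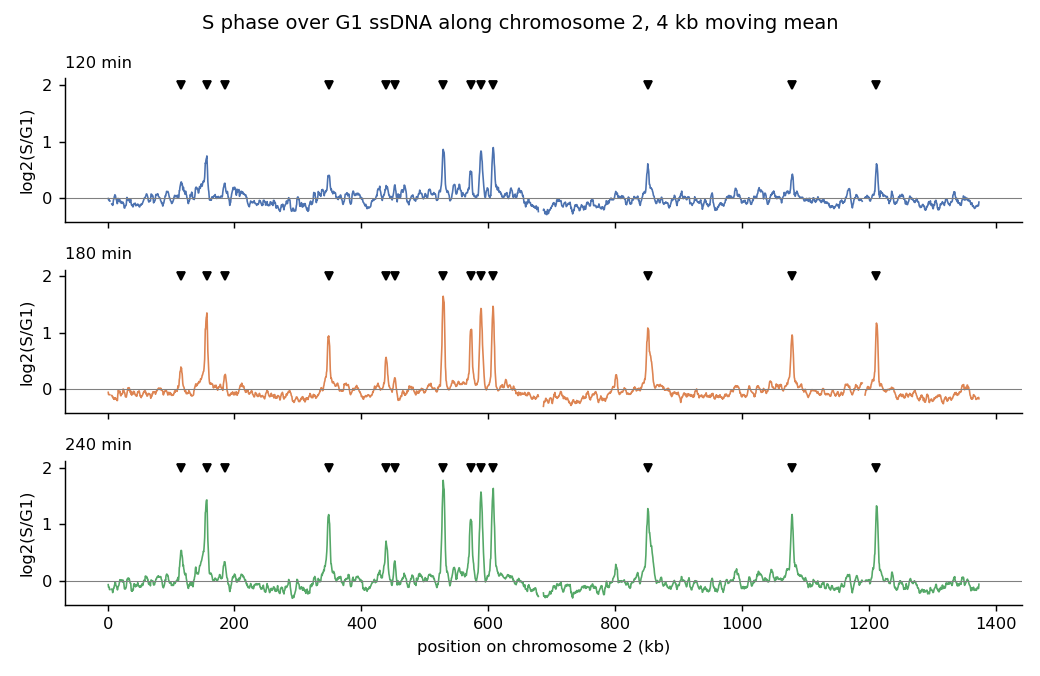
Smoothed log2(S/G1) (4 kb moving mean, average of both dye orientations) against position in kb on chromosome 2 at 120, 180 and 240 min, with triangles at the 13 summits of the mean track. The summits at 529000, 588500 and 607500 stood out at all 3 times.

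The test of single probes asked which sequences had a ratio common to the 3 time points. In limma, with Benjamini-Hochberg adjustment, 2306 of 32875 probes were higher in S phase and 2181 were lower. At an unadjusted p under 0.05 these counts were 4710 and 5661. The higher probes had a median ratio of 0.50. Of them, 1457 (63.2%) lay within 3 kb of a mean-track summit, and those had a median of 0.77. Summits were called on the same values, so this share describes the calls and is not independent evidence for the peaks. The lower probes were shallower, with a median of -0.28, and 7 of them lay within 3 kb of a summit, which the shared values also favour. Among the lower probes 10.2% lay within 20 kb of a chromosome end, against 2.73% of all tested probes. The adjusted counts depended on the 180 min arrays. Without the 180 min pair 1 probe was higher and 0 were lower, without 180 min replicate 2 both were 0, and without replicate 1 they were 476 and 3. At an unadjusted p under 0.05 in limma, 4635 and 4865 probes remained without the 180 min pair. For that pair the loss thus lay at the adjusted threshold. Without replicate 2 the unadjusted counts were 2538 and 1849, and without replicate 1 2505 and 1522. After adjustment the counts were 1207 and 315 without 120 min replicate 1. The lower probes numbered 1039 without 240 min replicate 1 and 665 without replicate 2. Without the 240 min pair they were 1029 and 152, and with the 180 min pair turned both were 0. Within slide 2, which held 180 and 240 min, they were 2963 and 2069.

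Peaks were already present at 120 min, and most of those called later lay at places called at 120 min. At 120 min 176 peaks were called above a height of 0.16, at 180 min 93 above 0.45 and at 240 min 140 above 0.19. The higher threshold at 180 min followed from the larger difference between its dye orientations, with an SD of 0.13 on the smoothed track against 0.05 at 120 min and 0.06 at 240 min. Around the mean-track summits the half-range of the 180 min arrays was 0.15 at the summit and 0.03 at 10 kb. The difference that set this threshold was thus not free of peak signal. The numbers of peaks therefore do not compare times on one scale. With local minima as the null instead, 72 peaks were called at 120 min, 106 at 180 min and 101 at 240 min. Without replicate 2, 294 were called at 120 min, against a dye-difference track that still used both arrays. Of the 93 summits at 180 min, 93 lay within 2 kb of a summit at 240 min, where shifted positions gave 5.64 on average. Of the 140 summits at 240 min, 114 (81.4%) lay within 2 kb of one at 120 min and 26 did not. Of the 93 at 180 min, 91 did. Of the 176 summits at 120 min, 91 lay within 2 kb of one at 180 min and 114 of one at 240 min, against 7.14 and 10.9 under shifts. The permutation p was 0.001 in each case, the smallest that 1000 shifts can give. A G1 DNA shared between time points would add to this overlap, and the labels do not say whether it was shared.

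By their median the 110 mean-track peaks were higher at later times. Their median height was 0.47 ± 0.02 at 120 min (1.38-fold), 0.97 ± 0.16 at 180 min (1.96-fold) and 1.07 ± 0.01 at 240 min (2.10-fold). From 120 to 240 min all 110 heights were higher, 108 of them with non-overlapping arrays, and 0 were lower with non-overlapping arrays. From 120 to 180 min 107 of the 110 heights were higher. With non-overlapping arrays 95 were higher and 0 lower, and 15 overlapped. These peaks were selected with the 180 and 240 min values. Of the 176 peaks called at 120 min, a choice that favours high values at that time, 101 were higher and 34 lower at 240 min with non-overlapping arrays, and 91 were higher and 45 lower at 180 min. Compared within each dye orientation, which was chosen after the data were seen, 106 of the 176 were higher and 51 lower in both orientations at 240 min, and 96 were higher and 59 lower at 180 min. The same comparison gave 110 higher and 0 lower of the mean-track peaks at 240 min, and 103 higher and 0 lower at 180 min. The ratio of median heights was 2.28 for 240 against 120 min, but 1.61 with each array in units of its own SD and 1.82 over the peaks called at 120 min. For 180 against 120 min it was 2.07, and 1.07 in SD units. That SD was taken over probes and includes the dye difference, which was largest at 180 min. It was 0.46 and 0.56 on the 180 min arrays, against 0.27 on each 120 min array. Ratios in SD units therefore do not correct for the scale of the signal alone. Comparisons with 120 min are also comparisons of slides.

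Of the 6 largest rises from 120 to 240 min, 5 were at peaks among the 12 highest of the mean track, whose height includes the 240 min value. The rises were 0.97 on chromosome 6 at 690000 and on chromosome 3 at 299000, 0.96 on chromosome 6 at 1016000, 0.95 on chromosome 4 at 780500, 0.92 on chromosome 2 at 529000 and 0.90 on chromosome 7 at 293500. At the last of these the height went from 0.64 ± 0.04 to 1.55 ± 0.04. No mean-track peak met the rule for a fall. The smallest rise, chosen after its value was seen, was 0.07 on chromosome 2 at 185000. Across the 110 peaks, which are not independent replicates, heights at 120 and 240 min correlated with r = 0.94.

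Between 180 and 240 min, within slide 2, the difference in height was small. The ratio of median heights was 1.10, 39 peaks were higher with non-overlapping arrays, 1 was lower and 70 overlapped. The dye effect was shared between times, so heights were also compared within each dye orientation, a comparison chosen after the data were seen. The median difference was -0.0075 on the arrays with S in Cy3, where 50 of the 110 peaks were higher at 240 min, and 0.27 on those with S in Cy5, where 107 were higher, and 48 were higher and 1 lower in both. In units of each array's SD, which includes the dye difference, the ratio was 1.51. Leaving out 180 min replicate 1, the ratio was below 1, at 0.90, so that the direction rested on that array.

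**Figure D3:**
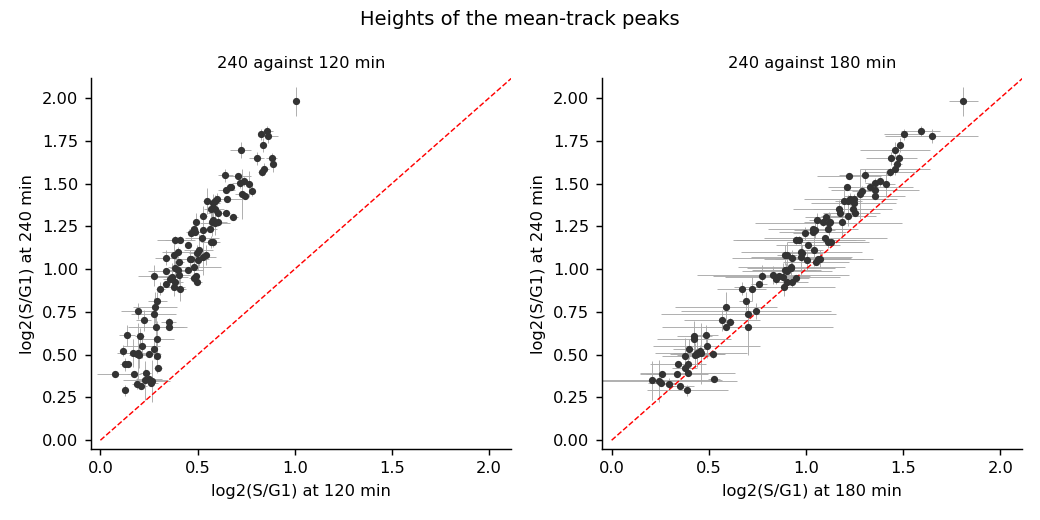
Height in log2(S/G1) of each of the 110 mean-track peaks at 240 min against 120 min (left) and 180 min (right), with half-ranges of the arrays as bars and a dashed line of equal height. All 110 peaks lay above the line against 120 min, and 100 against 180 min.

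The series design implied a comparison of the breadth of the ssDNA around each site, since forks that move outward carry it away from the summit. Around the mean-track summits the mean ratio of unsmoothed probes was 0.60 ± 0.01 at the summit at 120 min, 1.17 ± 0.15 at 180 min and 1.17 ± 0.02 at 240 min. At 2 kb it was 0.23 ± 0.02, 0.47 ± 0.10 and 0.63 ± 0.0016, and at 4 kb 0.09 ± 0.01, 0.15 ± 0.08 and 0.22 ± 0.01. From 180 to 240 min the summit differed by -0.01, with overlapping arrays, while the ratio at 2 kb was higher by 0.16, with both 240 min arrays above both 180 min arrays. Without 180 min replicate 1 the summit differed by -0.20 and without replicate 2 by 0.14, while the difference at 2 kb stayed above 0, between 0.07 and 0.25, whichever array was left out. At 4 kb the arrays of these times overlapped. From 120 to 240 min the arrays separated at every distance up to 6 kb, but the summit was also higher. As a percentage of the summit, the mean went from 37.6% to 54.2% at 2 kb, from 15.7% to 18.9% at 4 kb and from 10.0% to 8.91% at 6 kb, so at 6 kb the higher ratio was no broadening relative to the summit. Around the summits called at 120 min the difference at 2 kb was smaller, from 45.5% to 55.6%.

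Widths at 50% of the height had a median of 4.87 kb at 120 min, 4.75 kb at 180 min and 5.28 kb at 240 min, the last with both arrays (5.21 and 5.29 kb) above those of the earlier times. These widths include the 4 kb smoothing window. With a 2 kb window they were 3.25, 3.20 and 4.24 kb, and with an 8 kb window 8.70, 8.44 and 8.62 kb, which no longer put 240 min above 120 min.

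**Figure D4:**
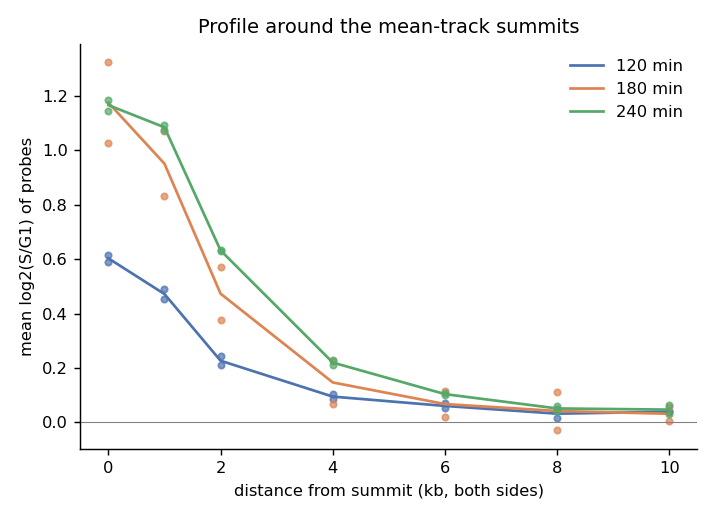
Mean log2(S/G1) of unsmoothed probes against distance in kb from the 110 mean-track summits at 120, 180 and 240 min, with a line for each time point's mean and a point for each array. At 2 kb the means were 0.23, 0.47 and 0.63, and at the summit those of 180 and 240 min were both 1.17.

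Chromosome ends had a lower S over G1 ratio than the rest of the genome on these arrays. Over the 16 ends the median of the outermost 20 kb was -0.14, against -0.01 for shifted positions (permutation p = 0.0008, adjusted p = 0.004 over 5 position tests). It was -0.13 at 120 min (arrays -0.12 and -0.12), -0.14 at 180 min, where the arrays differed most (-0.19 and -0.07), and -0.14 at 240 min (arrays -0.14 and -0.13). Of the 16 ends, 14 lay below 0. The lowest was the left end of chromosome 4 (510 to 20510) with -0.26 and the highest the left end of chromosome 7 (6715 to 26715) with 0.09. The median distance from an end to the nearest summit was 87.5 kb, against 31.2 kb for shifted positions (permutation p = 0.0098, adjusted p = 0.0163). An end can have summits on a single side only, and a shifted position on both, which by itself lengthens the distance from ends. This distance therefore cannot show a shortage of summits near ends. There was 1 summit within 20 kb of an end, against 3.47 under shifts (permutation p = 0.238, adjusted p = 0.238), which did not pass.

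The lowest point of the mean track also lay near an end, on chromosome 4 at 8000 (6000 to 10000), with -0.44. It was -0.45 ± 0.02 at 120 min, -0.38 ± 0.0036 at 180 min and -0.50 ± 0.02 at 240 min. The lowest point over 20 kb from an end, chosen after its value was seen, was on chromosome 1 at 954000 with -0.40. There the arrays read -0.48 and -0.52 at 120 min and -0.60 and -0.51 at 240 min, but -0.30 and 0.03 at 180 min.

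Sequence at the summits was compared through the probes, since the S. cerevisiae ARS consensus, WTTTAYRTTTW, marks replication origins in that yeast. Of the probes, 22 held an exact match. A match lay within 1 kb of 3 of the 110 summits, against 0.48 under shifts (permutation p = 0.0156, adjusted p = 0.0195). This depended on the distance: permutation p was 0.432 within 0.5 kb and 0.123 within 2 kb. With 1 mismatch allowed, 19 summits had a match within 1 kb (permutation p = 0.0216), and p was 0.411 within 0.5 kb and 0.119 within 2 kb by the same permutation test. Probes within 0.5 kb of summits had an AT content of 56.0%, against 55.2% at shifted positions (permutation p = 0.0024, adjusted p = 0.006).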

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

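The search below was set up after the peaks had been seen. Summits called at any time or in the mean track were examined, 273 in all. A summit that moved between lists was counted again, so this is not a number of separate places. Of these summits, 8 had both arrays of one time above 0 and both arrays of another time below 0. In all 8 the 180 min arrays were below 0 and those of 120 and 240 min above 0, and the differences were not tested. The 180 min values were -0.21 on chromosome 7 at 656500, -0.089 on chromosome 6 at 109500, -0.081 on chromosome 7 at 138000, -0.073 on chromosome 2 at 648500, -0.067 on chromosome 4 at 334500, -0.064 on chromosome 1 at 467500, -0.049 on chromosome 2 at 467500 and -0.021 on chromosome 4 at 505500. At 120 min these places ranged from 0.17 to 0.35, above the threshold of 0.16 there. They thus entered the search by being high at 120 min, a choice that favours lower values at other times. The 180 min pair had the largest difference between dye orientations.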

How the results depend on the processing

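The tests added after the data were seen included the 180 min pair with its sign turned and background-subtracted signals before dye normalization. The others were dye orientations for heights and the profile, the profile around summits called at 120 min, and further corrections at chromosome ends. Normexp, lowess, no centring and GC correction left all counts of peaks and probes within 1.5 times. So did the filters on dim and outlier spots and background-subtracted signals before dye normalization. The median at ends was -0.15 with normexp, -0.13 with lowess and -0.12 with GC correction, and other processing changes were not run for it. Its 9 alternatives also held distances of 10 and 40 kb, single time points, and points near summits left out. Over all 9 it stayed between -0.15 and -0.09, the latter with 40 kb. With the 180 min pair turned there were 0 peaks at 180 min, 16 in the mean track and 0 probes higher or lower. In the direction of the labels the 180 min track reached 1.81 at its highest and -0.38 at its lowest point, with a threshold of 0.45, so its troughs were too shallow to be called when turned; the mean track and the probe test then averaged opposed signs. With minima as the null 72 peaks were called at 120 min. Each array in units of its SD over probes, which includes the dye difference, gave other ratios of median heights. They were 1.07 (180 to 120 min), 1.61 (240 to 120 min) and 1.51 (240 to 180 min). Peaks called at 120 min gave 1.61 and 1.82 for the first pair of ratios, and peaks called at 240 min gave 2.53 for 240 to 120 min. Widths at 120, 180 and 240 min were 3.25, 3.20 and 4.24 kb with a 2 kb window and 8.70, 8.44 and 8.62 kb with an 8 kb window, as a window adds to the width. The ARS consensus lay near 1 summit within 0.5 kb (permutation p = 0.432) and 3 within 2 kb (permutation p = 0.123), and with positions of matched AT content its permutation p was 0.0238. With 1 mismatch the permutation p was 0.0216 within 1 kb, 0.411 within 0.5 kb and 0.119 within 2 kb. Probes lower in S numbered 4495 with a variance trend and robust moderation, and probes higher in S 4978 on the arrays with S in Cy3 alone. Higher and lower probes numbered 1 and 0 without the 180 min pair, 1029 and 152 without the 240 min pair, and 2963 and 2069 without the 120 min pair, each on 2 samples, so the number of samples alone does not account for the losses. The prior degrees of freedom of eBayes also differed between these fits, at 3.20, 7.25 and 14.8, and they limit how small a p-value can become. When single arrays were left out, the dye-difference track still used both arrays, so the left-out array still bore on the peak counts. Leaving out single arrays gave 216 to 294 peaks at 120 min, 91 to 131 at 180 min, 186 to 190 at 240 min and 105 to 122 in the mean track. It gave 0 to 2331 higher probes, 0 to 1666 lower probes, and ratios of 1.81 to 2.74 (180 to 120 min), 2.22 to 2.48 (240 to 120 min) and 0.90 to 1.26 (240 to 180 min). Widths then ranged from 4.67 to 5.01 kb, 4.51 to 4.84 kb and 5.21 to 5.30 kb at 120, 180 and 240 min, and the profile from 180 to 240 min from -0.20 to 0.14 at the summit and 0.07 to 0.25 at 2 kb. Except where named, the cause was not tested. Summits against genes and the other fixed regions were not run. Signal over background was high on all arrays, so the difference between dye orientations, largest at 180 min, limits the heights that can be called.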

Other observations

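Of the tests in this part, those of compressed signal at the highest peaks and of neighbouring heights were set before their results were seen, and the rest after. Besides the peaks of the mean track, 74 of the peaks called at 120 min lay outside it. Their medians were 0.20 at 120 min, 0.03 at 180 min and 0.14 at 240 min. Another 31 peaks called at 240 min lay outside the mean track, with medians of 0.18, 0.13 and 0.24. Both lists are highest at the time they were called at, which their choice favours, so no change with time can be read from them. Among the mean-track peaks, 6 were below the 120 min threshold at 120 min, with a median of 0.13, and had a median of 0.44 at 240 min. They were chosen for a low value at 120 min and a mean of the 3 times of at least 0.26. Higher values at the later times follow from that choice, so no change with time can be read from these peaks either.

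Heights of neighbouring peaks did not go together: over 102 neighbouring pairs r was -0.021, within the permuted range of -0.17 to 0.15 (5th to 95th percentile, permutation p = 0.92). The coefficient of variation of the spacing was 0.78, inside the range of 0.77 to 1.03 (5th to 95th percentile) for random placement with the same minimum distance, though near its lower bound (permutation p = 0.131). AT content at the higher 55 summits was 56.6% and at the lower 55 it was 55.4%, a difference of 1.17 percentage points that did not pass (permutation p = 0.0572). The sign patterns of the 3 time points number 4, too few for a share under 0.05: the real one gave 4487 probes past the threshold in limma, the highest other 0, and 1 of the 4 gave as many.

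The peaks were higher at 240 than at 120 min. A difference in scale between arrays or slides would stretch the track outside peaks as well, but over points more than 15 kb from any summit the slope of 240 on 120 min was 0.90 and the ratio of SDs 1.04, against a ratio of 2.28 for median peak heights and 2.20 to 2.43 over pairs of single arrays. This argues against scale alone. An effect of the slide on peaks alone cannot be told apart from time: within slide 2 the ratio of 240 to 180 min was 1.10, with 0.92 on the arrays with S in Cy3 and 1.25 on those with S in Cy5. Growth of ssDNA with time in hydroxyurea is a hypothesis that stays open beside it.

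The profile was broader at 240 than at 180 min with no higher summit on average, though the summit ratio of 240 to 180 min was 0.87 on the arrays with S in Cy3 and 1.16 on those with S in Cy5. Compression of the highest signals would spare low peaks, yet in the 36 lowest peaks the ratio of 240 to 180 min was 1.43 at 2 kb and 1.02 at the summit, with 1.10 against 0.86 in Cy3 and 2.08 against 1.26 in Cy5. Placement of summits by these same arrays is also argued against, since summits called at 120 min alone gave 1.38 at 2 kb and 1.10 at the summit. Outward movement of ssDNA is a candidate explanation: over all peaks the ratio was 1.34 at 2 kb (1.35 on the left, 1.32 on the right) and 0.99 at the summit, with 1.11 at 2 kb in Cy3 and 1.68 in Cy5, above the summit ratio on both sides in both orientations. It was found and tested on the same arrays, with 1 sample per time, and a difference in DNA preparation between these samples was not tested.

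Chromosome ends were lower in S phase at every time. A shortage of peaks near ends is argued against as the whole cause, because with points within 15 kb of a summit left out the ends had a median of -0.15, against -0.04 for shifted positions (permutation p = 0.0016). A shortage relative to ssDNA that builds up elsewhere with time stays open: the deficit against interior points far from summits had a ratio of 0.99 between 240 and 120 min (0.83 to 1.23 over pairs of arrays), but those points leave out the peaks and did not grow themselves. A feature of the G1 DNA or of the probes common to all arrays may account for it. The deficit differed by at most 0.021 between times and was positive on all 6 arrays, from 0.07 to 0.12. A shortage already present at 120 min would also give this. A dye effect on the probes would change sign between orientations, so the deficit in both orientations argues against it as the whole cause. G1 DNA held in low ammonium sulfate and S-phase DNA from rich medium also differ in medium, and that difference stays untested.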
